A study of Drosophila melanogaster with 4 samples.

How the data were processed

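Smc3 ChIP-seq was made from nuclei of Oregon-R larvae of instar 3 with an affinity-purified rabbit polyclonal antibody, per the labels. Crosslinked and sonicated chromatin was immunoprecipitated, and input DNA was sequenced beside it, per the labels' protocols. The 4 samples were grouped by their titles into 2 Smc3 ChIP samples and 2 Input samples. The free-text descriptions do not separate the groups: those of ChIP replicate 1 and Input replicate 1 name both ChIP DNA and input DNA, and those of ChIP replicate 2 and Input replicate 2 name input DNA alone. The titles were followed, and the source names give the same groups, so that replicate 2 is a ChIP sample rests on its title and source name and not on its description. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase release 5, per the file headers. The caller, its thresholds, the treatment of reads with several matches and the way the replicates were combined in the replicate-set list are not given in the sources used here.

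Each deposited list gave the chromosome, start, end and score of the enriched regions the authors called, 1 list for each ChIP replicate and 1 for the replicate set of the series. The score the authors deposited was read as a log2 value. For this, 2 to the power of the score was divided by 1 constant per list, 1.33 for each of the 3, and the result was a ratio of whole numbers for 99.9% of clusters in replicate 1, 99.9% in replicate 2 and 99.6% in the replicate-set list, within a tolerance of 1e-12 and with denominators up to 3000. The ratio is presumably ChIP over control, which the files do not state. The constant is not fixed by this fit alone, since its product with a simple ratio can fit as well. It was chosen among the most repeated scores by the share of whole-number ratios. Ties were settled by how evenly small prime factors fell in numerators and denominators. Sums of numerator and denominator depend on this choice. Reduced ratios lose common factors, so counts of reads were not taken from them. The depth of each sample is unknown, and no interval that needs it is given. Scores of named regions are given per list, each as a value within its own list. Between lists, scores were compared by correlation and, for X against the autosomes, as a difference in which the constant of each list drops out.

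Coordinates were kept 1-based as in the files. Clusters reaching past a sequence end were clipped there, 2 in each replicate and 3 in the replicate-set list. The 13 sequences with clusters were grouped into 5 major arms (2L, 2R, 3L, 3R and X), chromosome 4, 6 heterochromatic scaffolds (names ending in Het) and the unplaced sequence U. The proximal part of an arm was its 2 Mb at the centromeric end, the high end of 2L, 3L and X and the low end of 2R and 3R. A cluster counted as shared when it overlapped a cluster of the other list by at least 1 bp. Cover is the percent of bases inside clusters.

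Overlap between the replicates was tested by shuffling the clusters of the other list 1000 times within their own sequence with bedtools 2.31.1, without overlap among shuffled clusters. The reciprocal overlap rule was run with 200 shuffles. The shuffle could not place a median of 19 clusters of replicate 2 and 9 of replicate 1, so 2 further shuffles that place all clusters were added. Chance values per compartment, added after the data were examined, came from 1000 draws each. Clusters were moved by at most 250 kb on the major arms, passing round to the other end of the arm at a sequence end, and could then overlap each other. On the other sequences they were placed in random order with random gaps. The 14 p-values were adjusted together. Scores were correlated across clusters matched 1 to 1. Differences in cover between windows of 500 kb and in score between compartments were tested by permutation with 100000 resamples. The difference between X and the autosomes in the median score shift between replicates used 10000 resamples and an interval from 2000 bootstrap draws. The correlation and window alternatives also used 10000 resamples. Values over 5 arms or 6 scaffolds were tested by exact permutation. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only. Adjusted p-values are Benjamini-Hochberg values. All tests were two-sided except the overlap test, and the threshold was 0.05. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

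The procedures were tested on simulated data. A single simulated list was set against 40 independent lists, and 2.5% of these were called as overlapping. Lists with 20 percent of clusters copied gave a permutation p of 0.01 with 99 shuffles. The independent lists were made by the same random order and gaps that their test used, so a low rate was fixed in advance. This rate is not the error rate of the bedtools shuffle on lists dense in the same places. The X test called 100% of 40 draws with X covered 1.5 times as much and 7.5% of 40 draws with equal density. These draws held 5398 clusters, the number in replicate 1 outside the proximal 2 Mb, so the clusters of the dense proximal windows were left out. In replicate 1, cover of autosomal windows had an SD of 14.3 over whole arms and 2.83 without the proximal 2 Mb. The called shares therefore do not give the power or error rate of the whole-arm test. Whole-number ratios were found for 100% of 3000 simulated ratios and 0.0333% of 3000 random scores.

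Before the data were examined, the tests of shared clusters, shared scores, X against autosomes and the replicate-set list were fixed, with their alternatives. These were other overlap rules, score thresholds, equal list lengths, joined neighbours, fewer sequences, other windows and each replicate alone. The regions to be named were fixed as the 10 highest scores of the replicate-set list found in both replicates and the 5 widest shared clusters, taken here as the widest stretches inside 1 cluster of each replicate. The comparisons of heterochromatic scaffolds with major arms and of proximal with distal parts were added after the data were examined. So were the score tests between compartments, the score correlations by compartment and the regions named per arm. Promoters, gene locations and gene lists had been planned and were not analysed here, because the gene table used here is on release 6 of the genome and coordinates were not converted. No values were analysed here for the Input samples.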

Results

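Smc3 is a core subunit of cohesin, the ring-shaped complex that holds sister chromatids together and takes part in chromosome looping. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in larvae of instar 3 of the wild-type Drosophila melanogaster strain Oregon-R. The series held 4 samples, 2 Smc3 ChIP samples and 2 Input samples. Values were analysed here for the 2 ChIP samples, each with its own list of enriched regions (clusters), and for the authors' replicate-set list of the series. The Input samples were not analysed here as separate values. Replicate 1 held 7858 clusters with a median width of 2014 bp that covered 21.9 Mb, or 15.7% of the 13 sequences with clusters. Replicate 2 held 6505 clusters with a median width of 1811 bp that covered 20.6 Mb, or 14.7%. No cluster had the same start and end in both lists. The sequencing depth of the samples is unknown here. Nothing in the labels says whether the replicates came from separate collections of larvae, so the spread between them may be technical.

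The first comparison asked where along the genome Smc3 clusters lay. By percent of bases covered, clusters took up most of chromosome 4, the small and largely heterochromatic autosome, and a large part of most scaffolds of pericentric heterochromatin, the repeat-rich sequence around the centromeres. On chromosome 4, 75.5% ± 8.36 (SD, n = 2) of bases lay inside clusters. The scaffold 3LHet was covered to 66.3% ± 6.51, 2RHet to 53.9% ± 6.87, 3RHet to 53.3% ± 12 and 2LHet to 46.1% ± 9.84 (SD, n = 2 each). Among the 5 major arms, cover ran from 8.01% ± 1.93 on 3R to 13.7% ± 2.47 on 2R (SD, n = 2). XHet at 28.1% ± 11.6 and YHet at 11.2% ± 7.58 were less covered than the autosomal scaffolds, and the 5.80% of YHet in replicate 1 lay below every major arm. The unplaced sequence U was covered to 21.4% ± 5.81.

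Averaged over sequences, cover was 43.1% on the 6 heterochromatic scaffolds and 11.1% on the 5 major arms, a ratio of 3.89 (exact permutation test over all 462 splits, two-sided, p = 0.0216). The ratio was 2.93 in replicate 1 (exact permutation p = 0.0368) and 5.14 in replicate 2 (exact permutation p = 0.00433). This comparison was added after the data were examined, and sequences of one genome are not independent replicates. The labels and file headers do not state how reads from repeated sequence were placed.

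**Figure D1:**
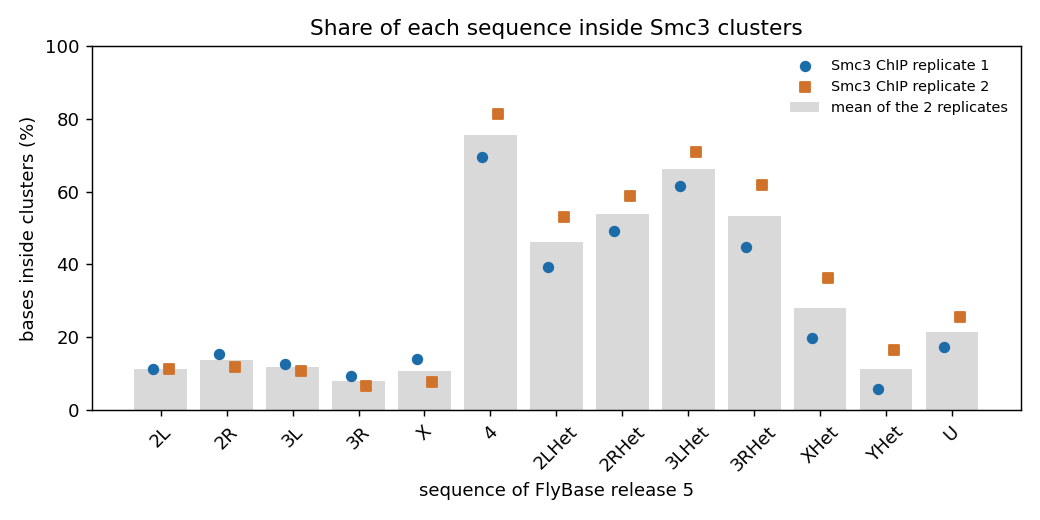
Percent of the bases of each FlyBase release 5 sequence (x axis) that lay inside Smc3 clusters (y axis), with replicate 1 as circles, replicate 2 as squares and the mean of the 2 replicates as grey bars. Chromosome 4 reached 69.6% in replicate 1 and 81.4% in replicate 2, while no major arm passed 15.4%.

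Within the major arms, cover was far higher towards the centromere on 2R, 3L and 2L than along the rest of the arm in both replicates, while on X and 3R the replicates went opposite ways. The proximal 2 Mb of 2R was covered to 68.5% ± 3.99 (SD, n = 2) and the rest of the arm to 7.93% ± 3.14. On 3L the shares were 60.4% ± 6.59 and 7.45% ± 2.02, and on 2L 38.4% ± 6.98 and 8.66% ± 0.756. On X the proximal part was covered to 11% in replicate 1 against 14.3% for the rest, and to 15.9% in replicate 2 against 6.78%. On 3R the shares were 8.83% against 9.41% in replicate 1 and 10.7% against 6.33% in replicate 2. Nearly all wide domains of the major arms lay in these proximal parts: 84 of the 84 clusters of at least 10 kb in replicate 1 and 110 of the 112 in replicate 2.

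The change along the arm was steep. On 2R, cover in the window from 1000001 to 1500000 was 84.5% in replicate 1 and 91.5% in replicate 2, and in the next window towards the arm it was 15.8% and 20.8%. On 3L, cover was 6.26% and 10.9% in the window from 22500001 to 23000000 and 71.5% and 84.0% in the window from 23000001 to 23500000. On 2L, the window from 22000001 to 22500000 held 44.2% and 60.7%, and the window before it 6.36% and 18.5%. Over the 5 arms, mean cover was 38.1% in the proximal 2 Mb and 8.49% in the rest, a ratio of 4.49, with the mean of the replicates higher in 5 of 5 arms (exact sign-flip permutation test, two-sided, p = 0.0625). That p is the smallest that 5 arms allow, so this design could not pass 0.05. In replicate 1 alone, 3 of the 5 arms were higher in the proximal part (ratio of means 3.37, exact permutation p = 0.25), and in replicate 2 alone 5 of 5 were (ratio of means 6.26, exact permutation p = 0.0625).

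**Figure D2:**
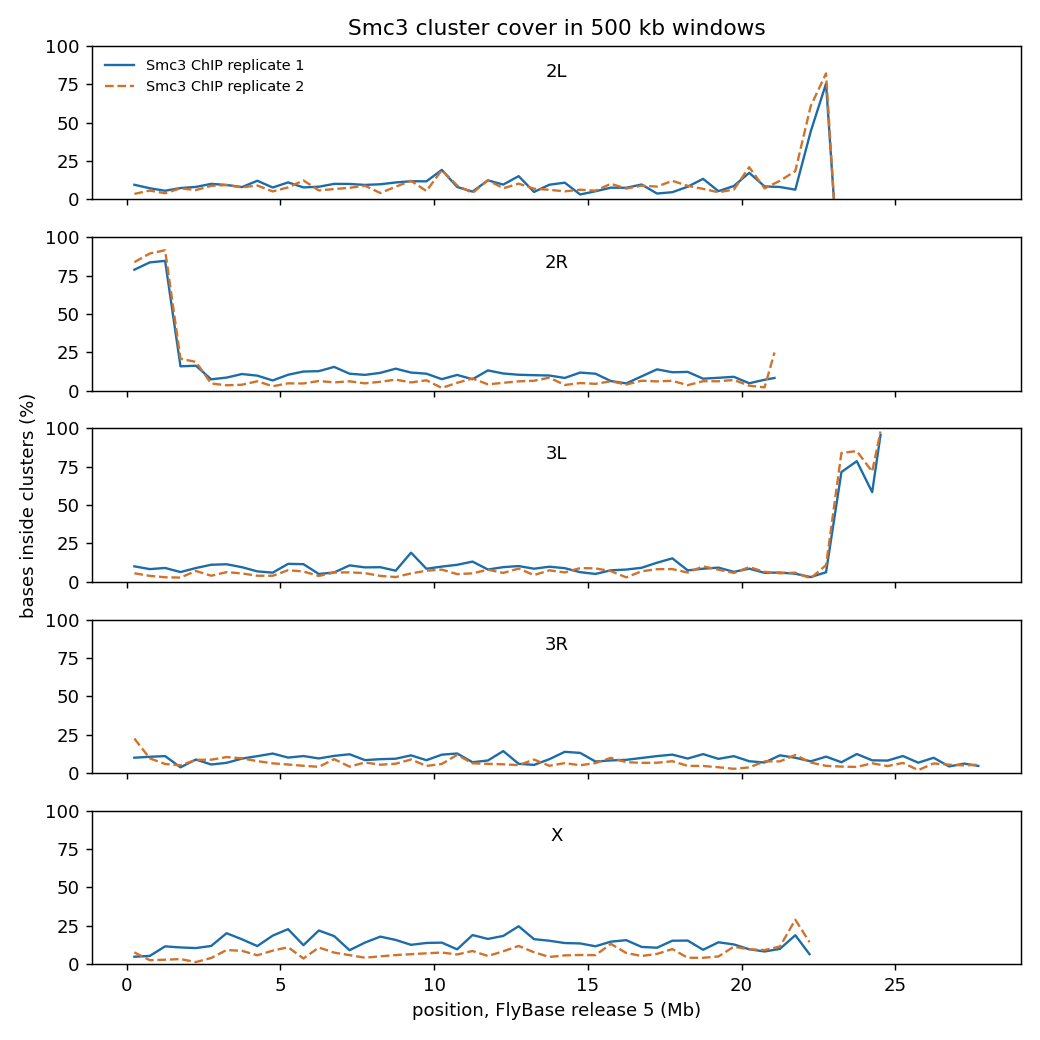
Percent of bases inside Smc3 clusters (y axis) in 500 kb windows along each major arm (x axis, position in Mb on FlyBase release 5), with replicate 1 as a solid line and replicate 2 as a dashed line. Cover was high at the centromeric ends of 2L, 2R and 3L, up to 98.0% in replicate 2 in the last and shorter window of 3L, while no window passed 29.0% on X or 22.5% on 3R.

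The authors' score, a log2 value per cluster, was also higher in these compartments than along the rest of the major arms, within each list. In replicate 1, clusters on the heterochromatic scaffolds had a mean score of 1.22 ± 0.35 (SD over 1014 clusters), those of the proximal 2 Mb 1.03 ± 0.34 (678 clusters) and those of chromosome 4 0.99 ± 0.35 (129 clusters). The 5398 clusters on the rest of the major arms had a mean score of 0.73 ± 0.26. In replicate 2 the same compartments had mean scores of 1.45 ± 0.47 (869 clusters), 1.05 ± 0.39 (704 clusters) and 1.08 ± 0.33 (135 clusters), and the rest of the arms 0.70 ± 0.19 (4009 clusters). Clusters on U had means of 1.44 ± 0.53 in replicate 1 and 1.66 ± 0.55 in replicate 2. Scores on U rested on ratios of smaller whole numbers, with a median sum of numerator and denominator of 71 and 62 after reduction, against 262 and 191 on the rest of the arms. On the heterochromatic scaffolds this sum was also smaller, at 163 in replicate 1 and 182.5 in replicate 2. Each of these 8 differences from the rest of the arms had p = 1e-05 in a two-sided permutation test (Benjamini-Hochberg adjusted 1e-05), the smallest that 100000 resamples can give. Clusters are not independent replicates, and wider clusters scored higher within each list (Spearman correlation across clusters 0.515 in replicate 1 and 0.519 in replicate 2).

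The widest stretch inside 1 cluster of each replicate lay on 2L from 22577097 to 22643842, a domain of 66.7 kb near the centromere with a score of 1.25 in replicate 1 and 1.53 in replicate 2. Chromosome 4 held the next, from 187430 to 245323 (57.9 kb, scores 1.5 and 1.61), and another from 455144 to 505789 (50.6 kb, 1.27 and 1.48). The remaining wide stretches of this set were on 3RHet from 1882224 to 1933451 (51.2 kb, 1.24 and 1.32) and on 2R from 957648 to 1004975 (47.3 kb, 1.28 and 1.46).

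Of the 10 replicate-set clusters with the highest scores among those found in both replicates, 5 lay on U, 3 on 3LHet and 2 on 3L. No cluster among the 100 highest scores of the whole replicate-set list was of this kind: 7 overlapped a cluster of either replicate and 0 overlapped clusters of both. The highest of the 10 was on U from 6478122 to 6481218, with scores of 2.62 in the replicate-set list, 3.87 in replicate 1 and 3.11 in replicate 2. The 3LHet regions started at 1395488 (replicate-set score 2.28, ending at 1399368), 1708114 (2.22, ending at 1711832) and 111622 (2.13, ending at 114238). The second highest of the 10 was the region on 3L from 21490642 to 21492900, at 2.54, outside the proximal 2 Mb. Its cluster scored 3.41 within the list of replicate 1 and 1.24 within that of replicate 2. The other region on 3L, from 24088554 to 24091636, had scores of 2.10 in the replicate-set list, 2.13 in replicate 1 and 2.58 in replicate 2.

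Outside the proximal parts, regions were taken per arm after their values were seen, as the replicate-set clusters with the highest scores found in both replicates. On 2L, the cluster from 6992742 to 6996580 scored 1.55 in replicate 1 and 1.74 in replicate 2, and the cluster from 10234288 to 10240704 scored 1.64 and 1.47. On 3L, the cluster from 14819530 to 14822052 scored 1.5 and 1.85. On 3R, the cluster from 3556328 to 3559408 scored 1.45 and 1.96, and the cluster from 12623430 to 12625700 scored 1.70 and 1.3. On X, the cluster from 6917466 to 6924632 scored 1.31 and 1.60, and the cluster from 10991902 to 10995900 scored 1.23 and 1.63. On 2R, the cluster from 2311424 to 2314838 scored 1.22 and 1.77. The widest replicate-set cluster of this kind was on 2L from 20098664 to 20125606, 26.9 kb long, over which each replicate held 5 clusters. The genes at these positions were not analysed here.

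**Figure D3:**
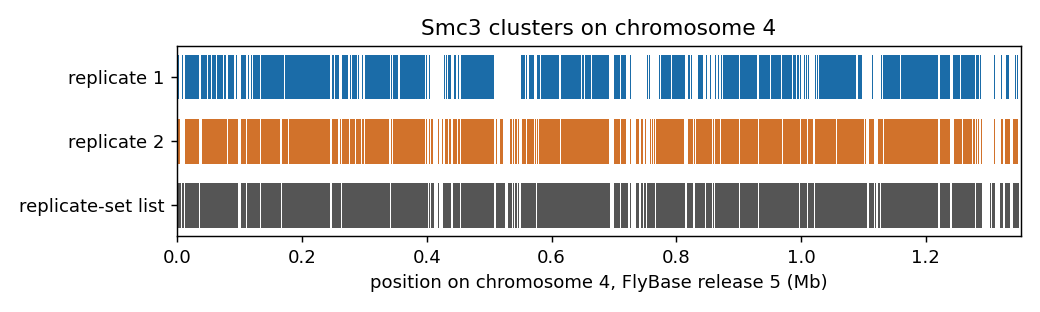
Clusters on chromosome 4 as filled blocks along the position in Mb on FlyBase release 5 (x axis), for replicate 1 (top row), replicate 2 (middle row) and the replicate-set list (bottom row). Clusters covered 69.6% of the chromosome in replicate 1, 81.4% in replicate 2 and 89.5% in the replicate-set list, and replicate 1 had its widest gap from 508405 to 551286.

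The next comparison asked how far the replicates placed clusters at the same positions. Of the clusters of replicate 1, 4073 or 51.8% (95% exact binomial interval 50.7 to 52.9) overlapped a cluster of replicate 2, and of those of replicate 2, 3549 or 54.6% (53.3 to 55.8) overlapped a cluster of replicate 1. By compartment, 95.1% of replicate 1 clusters on the heterochromatic scaffolds, 97.7% on chromosome 4, 82.3% in the proximal 2 Mb, 80.6% on U and 35.4% on the rest of the major arms were found in replicate 2. The reverse shares were 77.4%, 74.1%, 58.5%, 55.3% and 48.1%. On XHet and YHet together, 55.0% of the 20 clusters of replicate 1 and 22.4% of the 49 clusters of replicate 2 were shared. Both lists together placed 12.8 Mb inside clusters of each replicate, which was 58.5% of the bases of replicate 1 and 62.3% of those of replicate 2.

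Clusters shuffled within their own sequence gave lower overlaps, 29.3% ± 0.414 (SD over 1000 shuffles) for replicate 1 and 32.6% ± 0.483 for replicate 2. The observed shares were 1.77 and 1.67 times these values (permutation test, one-sided, p = 0.000999 for each, the smallest that 1000 shuffles can give). When each cluster of a pair had to overlap the other over its greater part, the shares were 34.1% and 41.2%, or 4.69 and 4.70 times chance (permutation p = 0.00498 for each, the smallest that 200 shuffles can give). Overlap by chance is frequent where much of a sequence is covered, so each compartment was also set against its own chance value, a test added after the data were examined.

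The ratio to chance cannot be ranked between compartments, because it is capped where the chance value is high. Sharing was 1.15 and 1.00 times chance on the heterochromatic scaffolds and 1.02 and 0.816 times chance on chromosome 4, for replicates 1 and 2. A count of clusters touching by 1 bp does not measure how well wide clusters coincide. On chromosome 4, for example, the stretch from 455144 to 505789 lay inside 1 cluster of each replicate. A ratio near or below 1 on these sequences therefore does not by itself show how far the replicates disagreed. Some replicate 2 clusters on chromosome 4 did fall in gaps of replicate 1. The gap of replicate 1 from 508405 to 551286, for example, held replicate 2 clusters such as that from 532749 to 536438. On the major arms outside the proximal 2 Mb, chance gave 13.7% for replicate 1 and 18.0% for replicate 2, and the observed shares were 2.58 and 2.67 times as high. On U the observed shares were 1.87 and 1.61 times the chance values of 43.0% and 34.3%, and in the proximal 2 Mb they were 1.54 and 1.36 times the chance values of 53.4% and 43.2% (permutation p = 0.000999, adjusted 0.00175, for each of these 6 shares). In the proximal 2 Mb, moved clusters could leave the dense blocks across their steep edges or round the sequence end. This can lower the chance value, so the excess there can come in part from both lists being dense in the same blocks. On the heterochromatic scaffolds, chance gave 82.9% for replicate 1, which was exceeded (permutation p = 0.000999, adjusted 0.00175), and 77.4% for replicate 2, which was not (permutation p = 0.502, adjusted 0.586). No shuffle left out stretches where reads cannot be placed. If both lists lack clusters in such stretches, the chance values are too low. The excess on U and on the scaffolds can come in part from this, which was not tested. On chromosome 4, chance gave 95.9% for replicate 1 (permutation p = 0.215, adjusted 0.334) and 90.8% ± 2.59 (SD over 1000 shuffles) for replicate 2, above the observed 74.1% (permutation p = 1, one-sided for an excess). XHet and YHet together did not exceed chance in either replicate (permutation p = 0.299 and 0.482, adjusted 0.418 and 0.586).

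Across clusters matched 1 to 1, the scores of the replicates were correlated, and the relation was weakest on the distal parts of the major arms. Over all 2685 matched pairs, Spearman's correlation was 0.551 and Pearson's 0.638. It was 0.754 over the 44 pairs of chromosome 4, 0.622 over the 310 pairs of U, 0.599 over the 225 pairs of the proximal 2 Mb and 0.420 over the 306 pairs of the heterochromatic scaffolds (Spearman). Over the 1800 pairs on the rest of the major arms it was 0.199, with Pearson's correlation at 0.268. Each of the 6 relations had a permutation p of 1e-05 (Benjamini-Hochberg adjusted 1e-05), the smallest that 100000 resamples can give. Clusters are not independent replicates, and the value over all pairs includes the difference in score between compartments. Scores spread least on the rest of the major arms (SD 0.26 in replicate 1 and 0.19 in replicate 2 over all clusters there), which can lower a correlation. Matching 1 to 1 left out many clusters, with 44 pairs from the 129 clusters of replicate 1 on chromosome 4. The correlations by compartment were added after the data were examined.

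**Figure D4:**
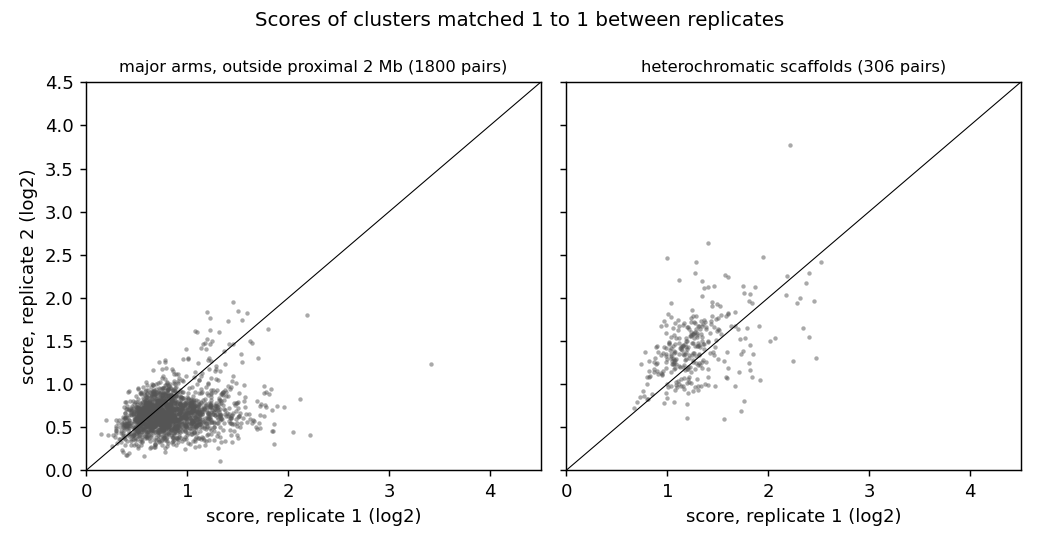
Authors' log2 score in replicate 1 (x axis) against replicate 2 (y axis) for clusters matched 1 to 1, each point 1 pair and the line marking equal scores. The left panel holds 1800 pairs on the major arms outside the proximal 2 Mb (Spearman 0.199) and the right panel 306 pairs on the heterochromatic scaffolds (Spearman 0.420).

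The X chromosome was compared with the autosomal arms in windows of 500 kb. Over whole arms, mean cover on X was 14.0% ± 4.41 (SD over 45 windows) in replicate 1 against 12.3% ± 14.3 on the 196 windows of 2L, 2R, 3L and 3R, a ratio of 1.13 (permutation p = 0.450, adjusted 0.600). In replicate 2 it was 7.62% ± 4.38 on X against 10.4% ± 16.5, a ratio of 0.736 (permutation p = 0.287, adjusted 0.573). Neither difference in cover passed the test, and the replicates went in opposite directions. Counted as cluster midpoints per window over whole arms, the ratio was 1.35 in replicate 1 (permutation p = 1e-04, the smallest that 10000 resamples can give) and 1.04 in replicate 2 (permutation p = 0.592). Without the proximal 2 Mb, a setting added after the data were examined, X was covered more than the autosomes in replicate 1, at 14.2% ± 4.26 against 9.38% ± 2.83 (ratio 1.52, permutation p = 1e-05, the smallest possible, adjusted 4e-05). In replicate 2 the values were 6.80% ± 2.71 and 6.62% ± 3.06 (ratio 1.03, permutation p = 0.724, adjusted 0.724). The adjusted values are Benjamini-Hochberg values over these 4 two-sided tests, and windows are not independent replicates. The difference between the replicates was tested on windows divided by the autosomal mean of their own list: on X they were higher in replicate 1 than in replicate 2 by 0.491 ± 0.413 (SD over 41 windows), in 37 of 41 windows (permutation test of X against autosomal windows, p = 1e-05, the smallest possible).

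The replicate-set list held more clusters than either replicate, 15783 in 39.9 Mb, or 28.5% of the sequence. It contained 97.1% of the clusters of replicate 1 and 96.4% of those of replicate 2. Of its own clusters, 3075 or 19.5% (95% exact binomial interval 18.9 to 20.1) were found in both replicates, 3585 or 22.7% in replicate 1 alone and 2566 or 16.3% in replicate 2 alone. The other 6557, 41.5% (40.8 to 42.3), were found in neither. Clusters found in both replicates were wide, with a median of 2975 bp and a median score of 0.76, and held 46.8% of the bases of the list. Those found in neither had a median width of 1229 bp and a median score of 0.50. Those found in replicate 1 alone had a lower median score, 0.44, and those found in replicate 2 alone one of 0.51. The major arms outside the proximal 2 Mb held 83.2% of the clusters found in neither, 92.5% of those in replicate 1 alone, 72.4% of those in replicate 2 alone and 61.3% of those in both, against 79.3% of the whole list. No test was made on these shares, and the intervals cover counting error only. The narrowest cluster was 1301 bp wide in each replicate list and 1001 bp in the replicate-set list. The median width of the clusters found in neither lay below 1301 bp, so the share found in neither does not measure replication alone.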

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

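Settings that remove or move parts of the arms were chosen after the data were examined. So were the shuffle that places all clusters in random order, the correlation on the heterochromatic scaffolds alone and all alternatives for the heterochromatic and proximal ratios. The excess of shared clusters over shuffled ones kept its direction and its side of the threshold in 9 of 9 alternatives for each replicate, with shares from 34.1% to 58.0% for replicate 1 and from 41.2% to 54.6% for replicate 2. The ratio to chance moved more, from 1.67 to 4.69 and from 1.45 to 4.70, and was highest with a reciprocal overlap rule. So did the correlation of scores in 5 of 5 (0.199 to 0.638) and the ratio of heterochromatic scaffolds to major arms in 8 of 8 (2.71 to 10.6, and 2.93 to 5.14 with 1 replicate). The proximal ratio ran from 3.37 to 11.5, and its p could not pass the threshold in any setting.

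Replicate-set clusters found in both replicates made up 15.6% when the greater part of a cluster had to be covered, 16.8% with the clusters at or above the median score of each list, 20.6% with neighbours joined and 16.5% on the main chromosomes. The shares found in neither were 43.7%, 50.8%, 39.9% and 42.7%. The stricter overlap rule can only lower the share in both and raise the share in neither, by construction. The setting by median score also removes replicate clusters that could have matched. For the other settings the cause was not tested. The ratio of X to autosomes in replicate 1 passed the threshold with cluster midpoints (1.35), without the proximal 2 Mb (1.52) and with equal list lengths besides (1.78). In replicate 2 it turned to 1.04, 1.03 and 1.03 in these settings, none past the threshold. The mean ratio of 0.935 ranged from 0.736 to 1.13 with 1 replicate left out, and turned above 1 without replicate 2. For the settings without the proximal 2 Mb, the high cover of these parts on 2L, 2R and 3L lowers the whole-arm ratio by construction. Midpoints count a wide cluster no more than a narrow one. Clusters of at least 10 kb numbered 13, 41 and 30 on 2L, 2R and 3L in replicate 1 and 21, 45 and 46 in replicate 2. On X there were 0 in each replicate, so midpoints raise the ratio by construction. Whether this is the whole change was not tested.

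With 1 replicate left out, no overlap or score correlation can be computed. Alternatives for promoters, gene locations and gene lists were not run. No paired analysis was possible because no values were analysed here for the Input samples, which share replicate numbers with the ChIP samples. The unknown depth limits what can be said of clusters missing from a list.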

Other observations

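The test of the heterochromatic pattern by score threshold, the test of X scores within each list, the test within groups of ratio sum, and the distal windows and gaps named here were chosen after the data were examined. Away from the centromeres, the windows of 500 kb with the highest mean cover of the 2 replicates were on 2L from 20000001 to 20500000 (17.3% in replicate 1 and 21.0% in replicate 2) and on 2L from 10000001 to 10500000 (19.2% and 19.1%). On 2R, the window from 2000001 to 2500000 held 16.2% and 18.7%. The X window from 12500001 to 13000000 held 24.8% in replicate 1, above both windows on 2L, and 11.9% in replicate 2. The lowest mean cover was on 3L from 22000001 to 22500000, at 3.09% and 2.33%, though in replicate 2 alone other windows were lower, such as X from 2000001 to 2500000 at 1.40%. Over the 219 windows outside the proximal 2 Mb, cover in the replicates was weakly correlated (Spearman 0.191, Pearson 0.295, permutation p = 0.00477 for Spearman). On chromosome 4, where most of the sequence was inside clusters, the widest stretches without a cluster in either replicate ran from 1289849 to 1308804 (19.0 kb) and from 522086 to 532748 (10.7 kb).

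The 100 highest scores of the replicate-set list were narrow and seldom found in the replicates. Their median width was 1041 bp, 66 of them lay on U, 7 overlapped a cluster of either replicate and 0 overlapped clusters of both. The numerator and denominator of their reduced ratio summed to a median of 9, against 315 over the whole list. The median width of these 100 clusters lay below the narrowest cluster of each replicate list, 1301 bp. The low share found in the replicates therefore does not measure replication alone.

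Heterochromatic scaffolds were covered 3.89 times as much as the major arms. If this rested on calls from ratios of small whole numbers, most called bases there would lie in such clusters. At most 6.12% did (reduced ratio summing to under 30, replicate 1), with 4.28% in replicate 2. This argues against cover resting on clusters whose own ratio was that small. It cannot decide on few reads per base, because wide clusters hold most weight and sums can grow with width. Median widths were 2881 and 3782 bp on the scaffolds against 1994 and 1636 bp on the rest of the arms, for replicates 1 and 2. Median sums were smaller on the scaffolds, 163 and 182.5 against 262 and 191. A looser score threshold on the scaffolds is argued against as well, since with clusters of score 1 or more the ratio was 7.95 in 1 replicate and 13.5 in the other. Scores were already known to be higher on the scaffolds when this test was chosen, so a higher ratio was to be foreseen. The test covers the score alone, and a looser threshold of another kind was not tested because the caller's thresholds are unknown here. Smc3 binding in heterochromatin, the placement of reads from repeated sequence and antibody background stay open as explanations that were not tested, and the design names no biological contrast for this pattern.

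Outside the proximal 2 Mb, X was covered more than the autosomes in replicate 1 and not in replicate 2. With replicate 1 cut to the length of replicate 2 by score, the ratio in replicate 1 divided by that in replicate 2 was 1.73. It was 1.48 with the lists as given, so the lowest-scoring clusters of replicate 1 did not make the difference. Whole-arm median scores in replicate 1 were 0.79 on X and 0.64 to 0.70 on the autosomal arms. A cut by score therefore favours X and cannot decide further on unequal list lengths. A candidate explanation is an enrichment on X, relative to the autosomes, that differed between the replicates. The scores that follow come from the same lists as the cover, so they are not independent support for it. Over clusters matched 1 to 1, the median of replicate 1 minus replicate 2 scores was higher on X (449 pairs) than on the autosomes (1351 pairs). The difference between these medians was 0.11 (95% bootstrap interval 0.068 to 0.16, permutation p = 1e-04, the smallest that 10000 resamples can give). Within each list, shared clusters on X had mean scores of 0.96 against 0.80 on the autosomes in replicate 1, and 0.70 against 0.65 in replicate 2 (permutation p = 1e-05 and 0.00012, adjusted 2e-05 and 0.00012), which leaves open whether replicate 1 or replicate 2 is unusual.

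On the same parts of the arms, replicate 2 clusters missing from replicate 1 scored higher than shared ones, with a mean difference of -0.055 for shared minus unshared, while in replicate 1 shared clusters scored higher by 0.18 (permutation p = 1e-05 for each, the smallest possible). Over all sequences the difference in replicate 2 had the opposite sign, 0.040 (permutation p = 0.0009). Unshared clusters rested on ratios of smaller whole numbers, with a median sum of numerator and denominator of 164 against 230. These smaller sums are argued against as the whole cause. The difference was -0.051 without the 323 of 4009 clusters summing to under 30 (permutation p = 1e-05). Averaged within 10 groups of the sum it was -0.046, below 0 in 8 of them (permutation p = 0.0005, the smallest that 2000 resamples can give). Width is argued against as the whole cause too, since the difference averaged within 10 groups of cluster width was -0.084 (permutation p = 0.0005). A part played by read depth, which reduced ratios measure only in part, a set of sites enriched in replicate 2 alone and a difference in library preparation stay open, and no biological explanation was tested because both replicates belong to 1 group.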
